A study of Homo sapiens with 13 samples.

How the data were processed

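The series holds 13 arrays of human prostate tissue, each hybridized with 1 tissue sample in the Cy5 channel and a commercial pool of benign prostate tissue in the Cy3 channel. The deposited values, 1 for each array feature, are log ratios of sample over pool and were taken as log2. They were extracted with Agilent Feature Extraction 8.5.1.1 per the submitters' processing notes, while background correction and dye normalization are not stated. The base of the logarithm is not stated either: the largest absolute value of 10.8 would be a ratio of over 10 decades in base 10, which an array scanner cannot record, so base 2 was used, and a natural logarithm cannot be ruled out from the values alone. On a natural scale every log2 change printed here would be larger by one constant factor, and no p-value would change. The printed folds would be larger, and the counts at a log2 change of at least 1 could change. Exactly 0 was listed for 13.7% of the values. This share was 2.11% for features of ribosomal protein genes and 37.6% for features of olfactory receptor and keratin-associated genes, so many zeros stand for spots with little signal, though the files do not say so. The median of every array was 0, which with this many zeros does not show that the arrays were centred. Arrays give no read depth; the number of arrays per group limits the precision, and signal over background was not used here.

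Of 45220 features 7960 had no value on any array. Of the 37260 with a value, 26558 had 1 gene symbol in the annotation supplied with the array, 73 had several symbols and 10629 had none, and the features without exactly 1 symbol were left out of the gene counts. Features of the Y chromosome and X inactivation transcripts, 65 in all, were left out. The remaining features stood for 17217 symbols. A feature needed a value on at least 3 arrays of each group, the features of a gene were averaged, and genes listed at 0 on every array were left out, which left 16918 genes. No genome build is stated for the array, so no coordinates are given.

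The groups follow the titles: benign (4 arrays, 2 titled benign and 2 titled normal), localized (5) and metastatic (4). The main comparison of cancer against benign, 9 against 4 arrays, was fitted with 2 groups as in the series design, and the others with 3 groups that share 1 estimate of the spread, or with 4 groups for normal against benign titles. Each used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with default settings, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, separately for each comparison; genes with an adjusted p below 0.05 are called. SE is the moderated standard error of the log2 change. Replicate numbers were not used for pairing, since the labels do not link samples.

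Fixed before the data were examined were the groups, comparisons, tests, the main alternatives, the 39 gene lists and the rule for the genes named. The lists cover cell types and tissues of the prostate and of sites where it spreads, and processes studied in prostate cancer, and were written from textbook knowledge; the methylation target lists of the series were not used here. The rule took the 10 highest and 10 lowest log2 changes among called genes for cancer against benign and for metastatic against localized, 6 each way for localized and metastatic against benign and 3 each way for normal against benign titles, the 4 members with the smallest p of each list that passed, of which 2 to 4 are printed, and 19 genes fixed in advance; symbols of unknown reading frames were passed over. Lists were tested with camera at a preset correlation of 0.01 between genes and with at least 5 measured members, adjusted over the 39 lists of a comparison, and again with the correlation estimated from the data. They were also tested with fry and with preranked enrichment by fgsea 1.28.0. Within each list, p-values were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

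The procedure was tested on simulated data with the same arrangement of arrays. Of 100 genes given a log2 change of 2, 53% were recovered in cancer against benign, 40% in localized against benign, 48% in metastatic against benign, 51% in metastatic against localized and 7% in normal against benign titles; for a change of 1 these shares were 12%, 9%, 8%, 8% and 0%. Between 1 and 4 of 16717 unchanged genes were called, and 0 of 50 random lists. The random lists were not chosen to hold genes that vary together, so they do not measure false calls of the lists tested here. Other divisions of the real arrays called a median of 10 lists for cancer against benign and 9 for localized against benign. The median was 9 for metastatic against benign and 10 for metastatic against localized.

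Alternatives fixed in advance were centring of the arrays on their median, quantile normalization, features with a value on all arrays, the most variable feature of each gene, no filter on missing values, variance with a trend and robust estimation, array weights, a log2 change of at least 1, the more variable 50% of the genes, a 3-group fit for cancer, only the arrays compared, only arrays of 1 title as comparison, a replicate block and leaving out each array. Centring on the median of values other than 0 and treating zeros as missing were added after the data were seen. The comparisons were also refitted on other divisions of the same arrays into groups of the same size, 100 drawn with a fixed seed or all 35 where there were fewer. Permutation tests of correlations used 100000 permutations within groups.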

Results

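Gene expression was measured in 13 human prostate tissue samples on 2-colour Agilent oligonucleotide arrays. Each array set 1 tissue sample against the same commercial pool of benign prostate tissue, so every value is a log ratio of sample over pool, taken as log2. A difference between groups is a difference between such ratios. The benign group held 4 arrays, 2 of them titled benign (B1 and B2) and 2 titled normal (N1 and N2). Localized prostate cancer had 5 arrays and metastatic prostate cancer had 4. The labels do not say whether the samples came from separate donors, so each p-value of a gene test below measures the spread between these samples. The camera p-values compare the members of a list with other genes. At the preset correlation they treat the members as nearly independent and do not measure that spread. With an estimated correlation no list was called in any comparison. The ratios spread more widely on the metastatic arrays (SD 1.34 to 1.55) than on the localized arrays (SD 0.88 to 1.15) and the benign arrays (SD 0.83 to 0.90). Between 10.5% and 19.5% of the values of an array were listed at exactly 0, with the highest shares on metastatic 3 and metastatic 4. Across genes, which are not independent replicates, the median correlation was 0.607 between localized arrays, 0.495 between benign arrays, 0.481 between metastatic arrays and 0.211 between benign and metastatic arrays. Pairs of metastatic arrays had correlations of 0.346 to 0.387 where metastatic 2 was in the pair and of 0.58 otherwise. After filtering, 16918 genes were tested in every comparison.

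The first comparison set the 9 cancer arrays against the 4 benign arrays, the contrast that the series design averages to rank genes. DLX1, a homeobox transcription factor, rose by 3.36 on the log2 scale (SE 0.42, 10.2-fold, adjusted p = 0.00582). Its level went from 0.14 ± 0.38 (SD, n = 4) in benign tissue to 3.50 ± 0.83 (SD, n = 9) in cancer, with all 9 cancer arrays above every benign array. DLGAP5, a protein of the mitotic spindle, rose by 3.39 (SE 0.65, 10.5-fold). COL10A1, a collagen known from growth-plate cartilage, rose by 3.08 (SE 0.49, 8.44-fold), and PBK, a mitotic kinase, by 2.77 (SE 0.44, 6.84-fold). KRT222, a keratin-like gene, fell by 3.68 (SE 0.42, 12.8-fold, adjusted p = 0.00437). The peptide hormone gene CCK fell by 4.29 (SE 0.58, 19.6-fold), and MYLK, the kinase that activates smooth muscle myosin, fell by 4.14 (SE 0.90, 17.7-fold). CYP3A7 and CYP3A4, cytochrome P450 enzymes that oxidize steroids and drugs, fell by 4.97 (SE 0.75, 31.4-fold) and 4.22 (SE 0.78, 18.6-fold).

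Further genes among the 10 largest increases were TMEM45B (4.88, SE 1.11), the cytokine gene IL11 (3.08, SE 0.62), the homeobox gene MNX1 (2.95, SE 0.64), the kinetochore gene SPC25 (2.85, SE 0.64) and CPNE7 (2.70, SE 0.59). HOXC6, another homeobox gene, was listed at 0 on all 4 benign arrays, while its level was 3.38 ± 0.26 (SD, n = 5) in localized and 1.78 ± 1.30 (SD, n = 4) in metastatic cancer. Among the 10 largest decreases, LIX1 changed by -4.09 (SE 0.71), CCDC178 by -3.79 (SE 0.75), the neuronal splicing factor RBFOX3 by -3.64 (SE 0.70), CHP2 by -3.60 (SE 0.75) and the basal keratin KRT15 by -3.46 (SE 0.61). Of the genes chosen in advance whatever their values, GSTP1, a glutathione transferase often methylated in prostate cancer, had levels of -0.49 ± 0.68 (SD, n = 4) in benign, -2.48 ± 0.62 (SD, n = 5) in localized and -2.79 ± 2.29 (SD, n = 4) in metastatic tissue. It did not pass (-2.13, SE 0.72, adjusted p = 0.162), and it was 0.64 on metastatic 2. AMACR, a peroxisomal racemase used as a marker of prostate cancer, had a change of 4.30 (SE 1.30, adjusted p = 0.116), and neither HPN (1.81, SE 0.62, adjusted p = 0.167) nor WFDC2 (-2.14, SE 0.59, adjusted p = 0.0831) passed. The transcription factor genes ERG (2.07, SE 0.97, adjusted p = 0.322) and ETV1 (-0.78, SE 0.79, adjusted p = 0.679) and KLK3, which encodes prostate-specific antigen (-0.69, SE 0.65, adjusted p = 0.658), were not called either. The maintenance methyltransferase gene DNMT1 had a change of 0.17 (SE 0.21) and DNMT3A of 0.24 (SE 0.21), neither past the threshold. Of the 19 genes chosen in this way, 5 were not analysed here.

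Among the 39 gene lists, 12 shifted in this comparison, 4 upward and 8 downward, and none kept its call with an estimated correlation between genes. Of the 45 measured proliferation genes 4 rose, among them CENPA (2.49, SE 0.44) and KIF4A (2.61, SE 0.49), none fell and 41 were not called. Adjusted over the list alone, 32 rose and 1 fell (mean 1.72, camera adjusted p = 3.39e-20, adjusted p = 0.285 with an estimated correlation). In the smooth muscle list 8 of 25 genes fell, including the contractile genes MYH11 (-2.76, SE 0.55), MYL9 (-2.55, SE 0.48) and SMTN (-2.07, SE 0.42), and 17 were not called. Of these 25 genes, 22 fell adjusted over the list alone (mean -2.63, camera adjusted p = 8.55e-20, adjusted p = 0.285 with an estimated correlation). Genes reported as promoter-hypermethylated in prostate cancer had a mean of -1.13 over 53 members (camera adjusted p = 1.21e-08, adjusted p = 0.344 with an estimated correlation). DPYS (-3.32, SE 0.48), CYP27A1 (-2.24, SE 0.37) and CAV1 (-3.13, SE 0.68) fell, TBX15 rose (2.03, SE 0.46) and 49 were not called. Adjusted over the list alone, 19 fell and 1 rose. Genes reported higher in prostate cancer had a mean of 0.98 over 35 members (camera adjusted p = 3.89e-06, adjusted p = 0.372 with an estimated correlation). Of these DLX1, DLX2 (1.97, SE 0.33) and HOXC6 (2.67, SE 0.56, against benign values that were all exact zeros) rose, while adjusted over the list alone 4 rose and 1 fell. In the basal epithelium list 5 of 16 genes fell, both over all genes and adjusted over the list alone, among them KRT14 (-1.72, SE 0.29), the urea transporter SLC14A1 (-1.82, SE 0.38) and DST (-1.65, SE 0.36), with a list mean of -1.27 (camera adjusted p = 8.9e-05, adjusted p = 0.561 with an estimated correlation). On metastatic 2 the mean of the basal list was 1.55, against -2.77 to -2.22 on the other metastatic arrays.

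In each of 7 further lists at most 1 member was called. DPT was the 1 of 22 fibroblast and extracellular matrix genes that fell (-2.73, SE 0.50, list mean -0.97, camera adjusted p = 0.000347, adjusted p = 0.561 with an estimated correlation, 6 fell adjusted over the list alone), beside PDGFRA (-1.23, SE 0.30, adjusted p = 0.0577). COL10A1 was the 1 of 15 reactive stroma genes that rose (mean 0.69, camera adjusted p = 0.0182, adjusted p = 0.561 with an estimated correlation, 3 rose adjusted over the list alone), beside FAP (1.89, SE 0.54, adjusted p = 0.0962). The glial gene S100B was the 1 of 8 peripheral nerve genes that fell (-3.36, SE 0.70, list mean -0.90, camera adjusted p = 0.00844, adjusted p = 0.285 with an estimated correlation, 2 fell adjusted over the list alone), beside PMP2 (-1.75, SE 0.46, adjusted p = 0.0712). GSTM3 was the 1 of 30 glutathione and metallothionein genes that fell (-2.40, SE 0.47, list mean -0.69, camera adjusted p = 0.00632, adjusted p = 0.529 with an estimated correlation, 7 fell adjusted over the list alone), beside GPX3 (-2.72, SE 0.64, adjusted p = 0.0553). No single member was called in the endothelium list (17 genes, mean -0.61, camera adjusted p = 0.000525, adjusted p = 0.372 with an estimated correlation, 4 lower adjusted over the list alone), the neuroendocrine list (18 genes, mean -1.12, camera adjusted p = 0.00207, adjusted p = 0.285 with an estimated correlation, 6 lower) or the hypoxia list (20 genes, mean 0.89, camera adjusted p = 0.000852, adjusted p = 0.561 with an estimated correlation, 0 adjusted over the list alone). The members with the smallest p were ROBO4 (-1.02, SE 0.25, adjusted p = 0.0585) and CLDN5 (-1.40, SE 0.34, adjusted p = 0.0599) in endothelium, BEX1 (-3.86, SE 0.89, adjusted p = 0.0525) and SNAP25 (-1.92, SE 0.46, adjusted p = 0.057) in the neuroendocrine list, and SLC2A3 (1.24, SE 0.34, adjusted p = 0.0815) and P4HA1 (1.88, SE 0.74, adjusted p = 0.236) in the hypoxia list. After quantile normalization the calls of reactive stroma (shift 0.81, adjusted p = 0.0784), endothelium (-0.21, 0.153) and peripheral nerve (-0.61, 0.133) were lost, and without localized 5 that of reactive stroma (0.49, 0.0847). The shifts of fibroblast (-0.57) and glutathione genes (-0.41) shrank after quantile normalization and stayed called. With only the arrays titled benign as comparison the call of peripheral nerve was lost (-0.61, 0.0572) and endothelium was -0.40 and called, and with only those titled normal the call of reactive stroma was lost (0.65, 0.0581).

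By limma, 225 genes changed between cancer and benign tissue, 39 (17.3%) of them higher, and 222 changed at least 2-fold. After quantile normalization 638 genes were called and 31.3% were higher. There were 976 with array weights, 123 with a trend and robust variance and 355 among the more variable 50% of the genes. A 3-group fit gave 992 or 1165, by the weights of the cancer groups, and only the arrays titled benign or normal as comparison gave 3 and 49. The count was 13, 23, 44 and 124 without benign N2, N1, B1 and B2. It was 74, 134, 146 and 91 without metastatic 1, 3, 4 and localized 3, and it was 392 without metastatic 2 and 489 without localized 5. Of the 37 named genes called here, DLX1, KRT222 and CCK kept their call in each of the 13 runs that left out 1 array. No direction turned, and all 37 kept their call under the other scalings, of which centring on the array median hardly changes the values. With the most variable feature per gene 5 calls were lost, those of MYLK, TMEM45B, SPC25, DST and TBX15. With zeros as missing 35 of the 37 could be tested, and these kept their call.

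**Figure D1:**
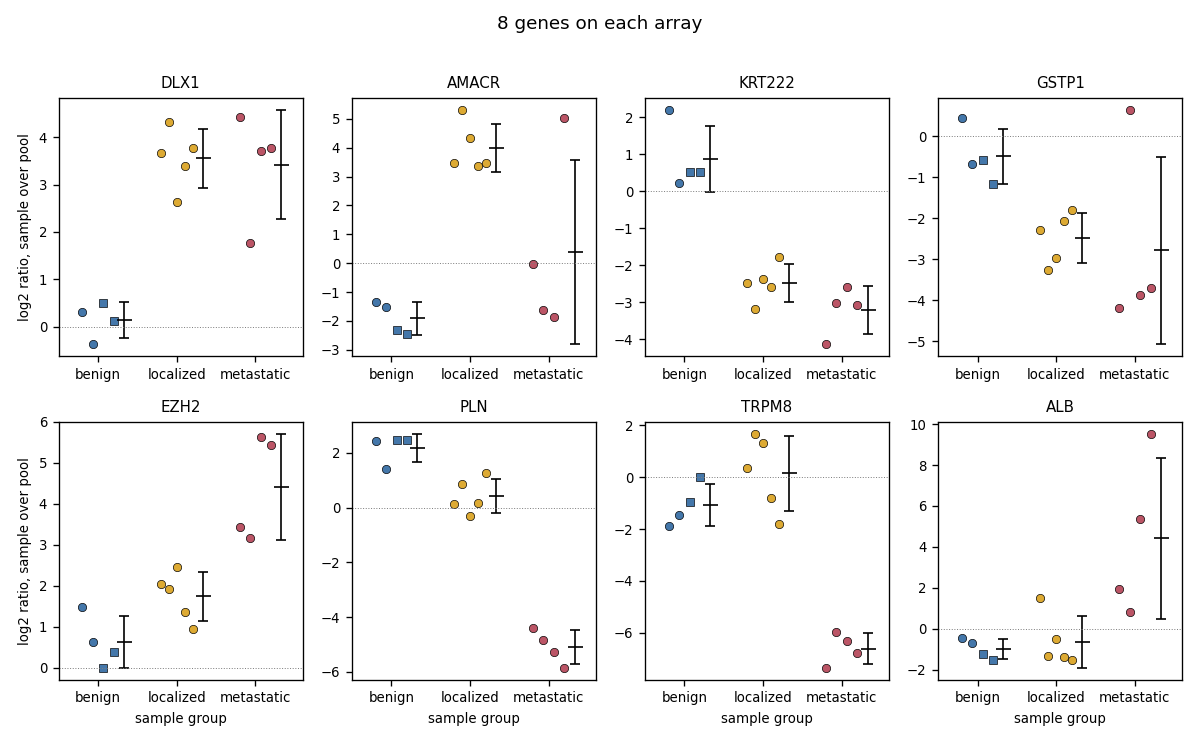
Log2 ratio of sample over pool for 8 named genes on each array, by group (circles, with squares for the 2 arrays titled normal; bars, mean and SD of the group). DLX1 was higher and KRT222 lower on all 9 cancer arrays than on any benign array, AMACR reached 5.03 on metastatic 4 and stayed at or below -0.03 on the other metastatic arrays, and GSTP1 was 0.64 on metastatic 2.

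The second comparison set the 5 localized cancer arrays against the 4 benign arrays. SLC45A2, a melanosomal transporter, rose by 2.49 (SE 0.38, 5.61-fold, adjusted p = 0.0204), from 0.50 ± 0.45 (SD, n = 4) to 2.99 ± 0.46 (SD, n = 5). DLX1 rose by 3.42 (SE 0.49, 10.7-fold), the homeobox gene HOXC5 by 3.30 (SE 0.50, 9.85-fold), COL10A1 by 3.04 (SE 0.56, 8.24-fold) and CCDC83 by 2.60 (SE 0.47, 6.08-fold). CYP3A4 fell by 4.87 (SE 0.79, 29.3-fold). Among the other decreases were CYP3A7 (-4.74, SE 0.85), CCK (-3.74, SE 0.57), DPYS, an enzyme of pyrimidine breakdown (-3.37, SE 0.55), KRT222 (-3.36, SE 0.44) and EDN3, a vasoactive peptide gene (-3.19, SE 0.58). AMACR had the largest change of the genes fixed in advance, 5.90 (SE 1.11, from -1.91 ± 0.57 to 3.98 ± 0.84), and lay above every benign array on all 5 localized arrays, but its adjusted p of 0.054 did not pass. GSTP1 (-1.99, SE 0.82, adjusted p = 0.382), HPN (2.22, SE 0.66, adjusted p = 0.187) and the antigen gene KLK3 (0.09, SE 0.57, adjusted p = 0.987) did not pass either.

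In localized cancer 13 lists shifted, 4 upward and 9 downward, none of them with an estimated correlation. The smooth muscle list had a mean of -1.71 over 25 genes (camera adjusted p = 2.59e-24, adjusted p = 0.118 with an estimated correlation). MYLK fell (-2.62, SE 0.41), 24 members such as CNN1 (-2.47, SE 0.46, adjusted p = 0.0523) were not called, and 21 fell adjusted over the list alone. Of the 35 genes reported higher in prostate cancer DLX1, DLX2 (2.08, SE 0.37) and HOXC6 (3.38, SE 0.46) rose and 15 rose adjusted over the list alone (mean 1.71, camera adjusted p = 2.23e-15, adjusted p = 0.06 with an estimated correlation). The change of HOXC6 is set against benign values that were all exact zeros. None of the 45 proliferation genes was called over all genes, among them PBK (2.50, SE 0.47, adjusted p = 0.054) and CENPA (2.02, SE 0.41, adjusted p = 0.0583), while 13 rose adjusted over the list alone (mean 0.99, camera adjusted p = 5.54e-14, adjusted p = 0.151 with an estimated correlation). In the promoter-hypermethylated list DPYS fell, CYP27A1 was not called (-1.95, SE 0.39, adjusted p = 0.0556), and adjusted over the list alone 12 fell and 1 rose (mean -0.79, camera adjusted p = 1.54e-06, adjusted p = 0.346 with an estimated correlation). No basal gene was called and 5 of 16 were lower adjusted over the list alone (mean -1.40, camera adjusted p = 1.64e-06, adjusted p = 0.588 with an estimated correlation), with KRT14 at -1.69 (SE 0.34, adjusted p = 0.0558) and KRT15 at -3.29 (SE 0.70, adjusted p = 0.0726). Immediate early genes, which respond quickly to stimuli and to tissue handling, had a mean shift of 0.86 over 24 members with none called over all genes or adjusted over the list alone (camera adjusted p = 0.000588, adjusted p = 0.686 with an estimated correlation). IER2 was 1.85 (SE 0.69, adjusted p = 0.316) and EGR3 was 2.39 (SE 0.98, adjusted p = 0.37). The list mean was 1.26, 1.51 and 1.63 on localized 2, 4 and 5, but -1.04 on localized 1 and 0.13 on localized 3. With only the arrays titled benign as comparison the call was lost (0.34, adjusted p = 0.335), and with only those titled normal the shift was 1.38. It was 1.30 without localized 1.

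The remaining 7 lists that shifted in localized cancer had no called member except COL10A1 in reactive stroma (list mean 0.88, camera adjusted p = 0.00395, adjusted p = 0.686 with an estimated correlation, 1 adjusted over the list alone), which also held BGN at 0.89 (SE 0.32, adjusted p = 0.295). Endothelium had a mean of -0.57 (camera adjusted p = 5.8e-05, adjusted p = 0.346 with an estimated correlation, 3 adjusted over the list alone), with a mean log2 ratio of -0.29 on localized 5 against -1.51 to -1.25 on the other localized arrays. Neuroendocrine genes had a mean of -1.02 (camera adjusted p = 0.000115, adjusted p = 0.118 with an estimated correlation), and adjusted over the list alone 6 were lower and 1 higher. Peripheral nerve genes had a mean of -0.88 (camera adjusted p = 0.00165, adjusted p = 0.157 with an estimated correlation, 3 adjusted over the list alone), fibroblast genes of -0.55 (camera adjusted p = 0.00401, adjusted p = 0.686 with an estimated correlation, 1), glutathione genes of -0.58 (camera adjusted p = 0.0109, adjusted p = 0.588 with an estimated correlation, 3) and 19 imprinted genes of -0.44 (camera adjusted p = 0.0146, adjusted p = 0.118 with an estimated correlation, 1). None of the following members was called: CLDN5 (-1.57, SE 0.38, adjusted p = 0.101) and ROBO4 (-0.96, SE 0.28, adjusted p = 0.172) in endothelium, BEX1 (-2.82, SE 0.80, adjusted p = 0.154) and SNAP25 (-1.81, SE 0.53, adjusted p = 0.168) among neuroendocrine genes, and S100B (-2.69, SE 0.69, adjusted p = 0.12) and PMP2 (-1.55, SE 0.51, adjusted p = 0.234) among nerve genes. The same held for DPT (-2.09, SE 0.41, adjusted p = 0.0556) and PDGFRA (-0.96, SE 0.29, adjusted p = 0.199) among fibroblast genes, GSTM3 (-2.19, SE 0.52, adjusted p = 0.0993) and GSTM5 (-2.47, SE 0.59, adjusted p = 0.0993) among glutathione genes, and PEG3 (-1.79, SE 0.46, adjusted p = 0.121) and MEG3 (-0.95, SE 0.30, adjusted p = 0.219) among imprinted genes. The fibroblast call was lost after quantile normalization (shift -0.39, adjusted p = 0.0981) and without benign B1 (-0.35, 0.154), localized 2 (-0.43, 0.0595) or localized 3 (-0.34, 0.0558). Leaving out 1 array also ended the calls of imprinted genes (benign B1, -0.41, 0.0557), glutathione genes (benign N1, -0.43, 0.0669, or localized 2, -0.43, 0.0943) and reactive stroma (localized 5, 0.53, 0.117). With only the arrays titled normal as comparison those of fibroblast (-0.47, 0.0855), imprinted (-0.45, 0.161) and glutathione genes (-0.63, 0.0543) were lost, and with the most variable feature that of imprinted genes (-0.48, 0.0585). Endothelium stayed called at -0.37 after quantile normalization and at -0.36 against the arrays titled benign alone, where peripheral nerve was -0.58 and called.

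By limma, 43 genes changed between localized cancer and benign tissue, 8 (18.6%) higher and 35 lower, all at least 2-fold. There were 267 after quantile normalization, 74 of them higher, 713 with array weights, 231 with only the arrays compared and 18 with a trend and robust variance. With only the arrays titled benign as comparison 0 were called by limma. There 983 had an unadjusted p below 0.05, where 846 are expected by chance. The count was 1 without benign N2, and 14, 19, 20, 28 and 16 without benign B1, benign N1, localized 2, localized 3 and localized 4. It was 169 without metastatic 2, which enters the shared estimate of the spread. None of the 14 named genes called here kept its call in all 13 runs that left out 1 array. DLX1, HOXC6 and KRT222 lost it only without benign N2, and no direction turned. All benign values of HOXC6 were exact zeros, so its call rests on them, and with zeros as missing it had no benign value. With zeros as missing 10 of the 14 genes could be tested, and these kept their call. The most variable feature per gene ended the calls of CCDC83, COL10A1, DPYS and EDN3.

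The third comparison set the 4 metastatic cancer arrays against the 4 benign arrays. PLN, a regulator of the calcium pump of muscle, fell by 7.28 (SE 0.41, 155-fold, adjusted p = 3.3e-06). Its level went from 2.19 ± 0.52 (SD, n = 4) to -5.09 ± 0.62 (SD, n = 4). PCP4, a calmodulin-binding protein, fell by 7.24 (SE 0.49, 151-fold). Large decreases were also seen for the prostate transcripts PCAT4 (-7.63, SE 1.15), PAGE4 (-7.34, SE 0.72) and MSMB (-7.08, SE 1.15). SYNM, an intermediate filament gene, fell by 6.58 (SE 0.56). EZH2, the methyltransferase of the polycomb complex, rose by 3.79 (SE 0.57, 13.8-fold, adjusted p = 0.00109). The de novo DNA methyltransferase gene DNMT3B rose by 2.86 (SE 0.55, 7.24-fold) and TOP2A, a topoisomerase of dividing cells, by 3.05 (SE 0.64, 8.27-fold). The largest increases were FGG, a fibrinogen chain (6.75, SE 1.23), TM4SF4 (6.64, SE 0.85), GPRC5A (5.80, SE 0.80), DQX1 (5.62, SE 0.84), ALB, the gene of serum albumin (5.39, SE 1.45), and HILPDA, a lipid droplet gene induced by hypoxia (5.28, SE 0.90). Albumin was uneven within the group, with log2 ratios of 1.95, 0.83, 5.36 and 9.54 on metastatic 1 to 4.

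In metastatic cancer 15 lists shifted against benign tissue, 4 upward and 11 downward, none of them with an estimated correlation. Of the 45 proliferation genes 35 rose, 10 were not called and none fell, with NUSAP1 at 3.90 (SE 0.47), CDCA8 at 3.65 (SE 0.42) and CENPF at 3.62 (SE 0.43). Here 40 rose and 2 fell adjusted over the list alone (mean 2.62, camera adjusted p = 2.1e-27, adjusted p = 0.104 with an estimated correlation). In the smooth muscle list 21 of 25 genes fell, and 23 fell adjusted over the list alone (mean -3.78, camera adjusted p = 8.57e-23, adjusted p = 0.164 with an estimated correlation), including MYLK (-6.05, SE 0.43), CNN1 (-5.98, SE 0.49) and MYH11 (-3.40, SE 0.57). Of the 20 hypoxia genes 9 rose, such as the prolyl hydroxylase gene P4HA1 (3.48, SE 0.31), PFKFB3 (2.40, SE 0.35) and ADM (5.03, SE 1.01), and 13 rose adjusted over the list alone (mean 1.78, camera adjusted p = 2.94e-08, adjusted p = 0.22 with an estimated correlation). In the promoter-hypermethylated list 22 genes fell, 1 rose and 30 were not called, with SFRP1 at -4.77 (SE 0.43), SLIT2 at -3.05 (SE 0.43) and TIMP3 at -2.19 (SE 0.30). Adjusted over the list alone 31 fell and 2 rose (mean -1.55, camera adjusted p = 8.75e-08, adjusted p = 0.333 with an estimated correlation). GSTP1, a member of that list, was not called (-2.30, SE 0.87, adjusted p = 0.0969). Of 18 WNT antagonists and stem regulators 7 fell, over all genes and adjusted over the list alone, among them SFRP1, SFRP2 (-3.84, SE 0.59) and the WNT receptor gene FZD7 (-2.18, SE 0.34, list mean -1.15, camera adjusted p = 0.00496, adjusted p = 0.22 with an estimated correlation).

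The hepatocyte list rose against benign tissue (17 genes, mean 2.33, camera adjusted p = 0.000739, adjusted p = 0.504 with an estimated correlation): 4 genes rose, among them FGG, ALB and APOC3 (4.05, SE 1.05), CYP3A4 fell (-3.40, SE 0.84) and 12 were not called. Adjusted over the list alone 8 rose and 1 fell. The list mean was 5.54 on metastatic 4 and 1.62, 0.59 and 0.07 on metastatic 3, 1 and 2, and without metastatic 4 the shift was 1.14 and called. Of 14 erythroid and marrow genes ALAS2 (2.49, SE 0.73) and CA1 (2.69, SE 0.81) rose, and 4 rose adjusted over the list alone (mean 1.13, camera adjusted p = 0.00331, adjusted p = 0.501 with an estimated correlation). The list means were 0.40 and 0.20 on metastatic 2 and 4 against -1.47 and -1.33 on metastatic 3 and 1. ALAS2 lost its call in all but 4 of the 13 runs that left out 1 array (it held without localized 3, localized 5, metastatic 1 or metastatic 3). CA1 held only in the runs without metastatic 1, 3 or 4, and was 1.64 without metastatic 4. Of 5 mast cell genes 4 fell, over all genes and adjusted over the list alone, such as CPA3 (-4.77, SE 0.50) and HDC (-4.08, SE 0.64, list mean -2.78, camera adjusted p = 0.00113, adjusted p = 0.22 with an estimated correlation). Of 13 T and NK cell genes 6 fell and 7 adjusted over the list alone, such as GZMA (-3.80, SE 0.83) and GZMK (-2.39, SE 0.53, list mean -1.32, camera adjusted p = 0.0156, adjusted p = 0.536 with an estimated correlation). The T and NK cell list had means of -1.61 and -1.21 on the arrays titled normal and of -0.014 and -0.063 on those titled benign. Against the arrays titled normal alone its shift was -0.64 (adjusted p = 0.399), and against those titled benign alone -2.00. Of 12 B and plasma cell genes 5 fell and 7 adjusted over the list alone, such as JCHAIN (-6.21, SE 0.66) and CD38 (-5.56, SE 0.90, list mean -1.78, camera adjusted p = 0.0165, adjusted p = 0.501 with an estimated correlation). In the luminal epithelium list 4 of 18 genes fell, MSMB, DPP4 (-4.52, SE 0.65), ACP3, which encodes prostatic acid phosphatase (-3.64, SE 0.84), and AZGP1 (-2.71, SE 0.63). There 7 fell adjusted over the list alone (mean -1.59, camera adjusted p = 0.0156, adjusted p = 0.501 with an estimated correlation). Fibroblast genes had 10 of 22 members lower and 1 higher, with MFAP4 at -3.68 (SE 0.45) and DPT at -3.54 (SE 0.43), and adjusted over the list alone 12 fell and 2 rose (mean -1.50, camera adjusted p = 0.000151, adjusted p = 0.501 with an estimated correlation).

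Glutathione genes had 7 members lower, such as GSTO1 (-1.68, SE 0.29) and GSTM3 (-2.66, SE 0.55), and 2 higher, with 11 and 2 adjusted over the list alone (mean -0.83, camera adjusted p = 0.0423, adjusted p = 0.504 with an estimated correlation). In endothelium 5 genes fell, such as EMCN (-2.87, SE 0.58) and VWF (-1.65, SE 0.38), and 6 adjusted over the list alone (mean -0.66, camera adjusted p = 0.0423, adjusted p = 0.536 with an estimated correlation), but after quantile normalization its mean was 0.0016 (adjusted p = 0.872). In basal epithelium 5 genes fell, over all genes and adjusted over the list alone, such as KRT15 (-3.67, SE 0.73) and KRT14 (-1.75, SE 0.35, list mean -1.11, camera adjusted p = 0.0423, adjusted p = 0.655 with an estimated correlation). The list mean was 1.55 on metastatic 2 against -2.77 to -2.22 on the other metastatic arrays, and the shift was -2.13 without metastatic 2, -0.70 without metastatic 1 and -0.71 without metastatic 3. Quantile normalization also ended the calls of the luminal (shift -1.02, adjusted p = 0.107), basal (-0.49, 0.156), T cell (-0.45, 0.537), B cell (-0.90, 0.537) and glutathione (-0.30, 0.167) lists. It left called but moved the fibroblast (-0.81), mast cell (-1.81), promoter-hypermethylated (-0.87), WNT (-0.56) and erythroid (1.76) lists. Leaving out metastatic 2 ended the calls of luminal (-1.15, 0.16) and erythroid genes (0.82, 0.0564). Each of several single arrays did so for basal genes (benign B1 and metastatic 1, 3 or 4, adjusted p = 0.0785 to 0.24), endothelium (benign B1 or N1, localized 3 or any metastatic array, 0.0507 to 0.085), glutathione genes (benign B1 or N1 and metastatic 1, 3 or 4, 0.0538 to 0.217), T cell genes (benign B1, 0.0785, or metastatic 4, 0.085) and B cell genes (benign B1, 0.0552). Against the arrays titled benign alone the calls of endothelium (0.146) and glutathione genes (0.0701) were lost, and with only those titled normal also those of basal (0.114), B cell (0.076) and glutathione genes (0.0946). The most variable feature ended those of luminal, basal and endothelium (0.0543 each) and glutathione genes (0.0702), and zeros as missing those of basal (0.0661) and glutathione genes (0.0861).

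By limma, 2441 genes changed between metastatic cancer and benign tissue, 824 (33.8%) higher and 1617 lower. With the arrays centred on the median of their values other than 0, which moved the median of all genes by 0.15, the share of higher genes among 2466 was 45.8%, and after quantile normalization it was 44.9% of 1950. The count was 1463 without benign N1, 1527 without benign N2 and 1418 with only the arrays compared. It was 759 and 1452 with only the arrays titled benign or normal as comparison. Of the 67 named genes called here 59 kept their call in all 13 runs that left out 1 array and 52 under every other scaling, and no direction turned. ALB lost its call in 4 of the 13 runs (benign B2, N1 and N2 and metastatic 3) and ranged from 3.69 to 6.59. APOC3 lost its call in 2 (benign B2 and N2). Quantile normalization ended the calls of ACP3, AZGP1, GZMA, GZMK, VWF and TOP2A among the genes given above. VWF was -0.36 there and -2.92 with the most variable feature.

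**Figure D2:**
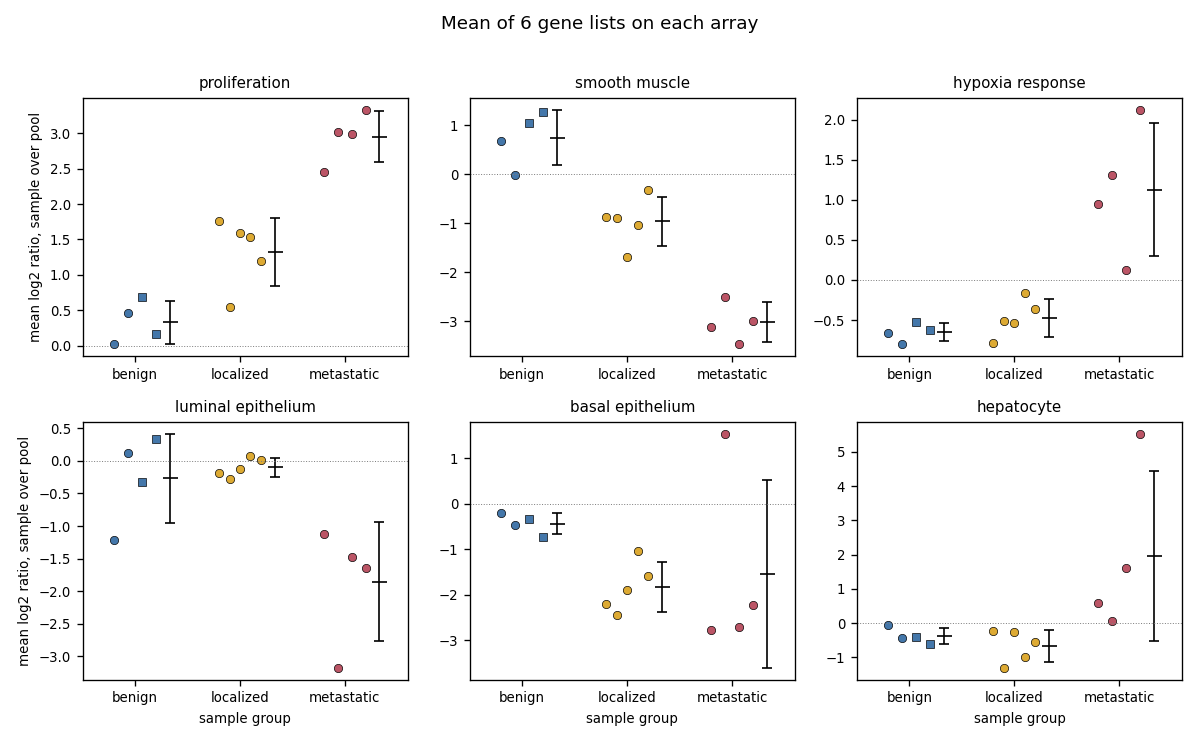
Mean log2 ratio of sample over pool of 6 gene lists on each array, by group (circles, with squares for the 2 arrays titled normal; bars, mean and SD of the group). Every metastatic array lay above every other array for proliferation and hypoxia genes and below every other array for smooth muscle genes, metastatic 2 stood at 1.55 for basal and -3.18 for luminal genes, and metastatic 4 stood at 5.54 for hepatocyte genes.

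The fourth comparison, between the 4 metastatic and the 5 localized arrays, is also the test of whether both cancer groups differ from benign tissue to the same extent. TRPM8, an androgen-regulated cation channel gene, fell by 6.76 (SE 0.66, 108-fold, adjusted p = 0.000335). Its level went from 0.15 ± 1.45 (SD, n = 5) to -6.61 ± 0.60 (SD, n = 4). The olfactory receptor gene OR51E2, which is abundant in prostate, fell by 6.79 (SE 1.25, 111-fold). Further decreases were PAGE4 (-6.56, SE 0.68), CD38 (-6.02, SE 0.86), THBS4 (-5.97, SE 0.93), LUZP2 (-5.78, SE 0.92), MMP26 (-5.27, SE 1.14) and the lymphocyte activation gene CD69 (-5.02, SE 0.60). DDIT4, a stress-induced inhibitor of mTOR signalling, rose by 4.50 (SE 0.43, 22.7-fold, adjusted p = 0.000335), FBXL16 by 4.64 (SE 0.66), TM4SF4 by 6.82 (SE 0.81), DQX1 by 4.84 (SE 0.80) and HILPDA by 4.81 (SE 0.86). EZH2 rose by 2.67 (SE 0.54, 6.35-fold) and DNMT3B by 2.11 (SE 0.52, 4.32-fold). AMACR (-3.60, SE 1.11, adjusted p = 0.0666), KLK3 (-1.75, SE 0.57, adjusted p = 0.0805) and GSTP1 (-0.31, SE 0.82, adjusted p = 0.864) did not pass.

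Between metastatic and localized cancer 17 lists shifted, 6 upward and 11 downward, none of them with an estimated correlation. Of the proliferation genes 23 of 45 rose and 35 adjusted over the list alone (mean 1.63, camera adjusted p = 5.39e-21, adjusted p = 0.21 with an estimated correlation), such as CDC20 (2.49, SE 0.38), CENPF (2.66, SE 0.41) and E2F1 (2.44, SE 0.38). Of the hypoxia genes 9 of 20 rose and 10 adjusted over the list alone (mean 1.60, camera adjusted p = 1.56e-09, adjusted p = 0.21 with an estimated correlation), such as P4HA1 (2.87, SE 0.30), ANGPTL4 (4.10, SE 0.61) and the glycolytic gene PGK1 (2.23, SE 0.35). In the hepatocyte list FGG (6.67, SE 1.17), HP (5.86, SE 1.37), ALB (5.06, SE 1.37) and APOC3 (4.30, SE 0.99) rose, 13 were not called and 7 rose adjusted over the list alone (mean 2.62, camera adjusted p = 5.41e-07, adjusted p = 0.365 with an estimated correlation). Without metastatic 4 the shift was 1.43 and called. Beside them, AKR1B10 (5.16, SE 1.43) was highest on metastatic 2 at 7.63, and the fatty acid carrier gene FABP1 (4.90, SE 1.39) was called as well. Of the 13 runs that left out 1 array, the calls of AKR1B10 and FABP1 held only in those without metastatic 1, 2 or 4, and that of ALB only in those without localized 1 or metastatic 1, 2 or 4. Without metastatic 4, FABP1 was 3.04 and ALB 3.35, and without metastatic 2, AKR1B10 was 3.20. Quantile normalization ended the calls of FABP1 and ALB. HBB rose (3.08, SE 0.81) among 14 erythroid genes, with HBD at 3.22 (SE 0.95, adjusted p = 0.0566) and 7 adjusted over the list alone (mean 1.20, camera adjusted p = 0.00011, adjusted p = 0.353 with an estimated correlation). PRAME rose (3.81, SE 0.77) among 23 cancer-testis genes, both over all genes and adjusted over the list alone (mean 0.54, camera adjusted p = 0.0447, adjusted p = 0.21 with an estimated correlation), while DDX43 was -2.29 (SE 0.72, adjusted p = 0.0723). Of 15 genes of lipid and sterol synthesis none was called and 2 rose adjusted over the list alone (mean 0.51, camera adjusted p = 0.0327, adjusted p = 0.374 with an estimated correlation), with SCD at 1.92 (SE 0.57, adjusted p = 0.0595) and SQLE at 1.53 (SE 0.47, adjusted p = 0.0649).

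Among lower lists, 14 of 25 smooth muscle genes fell and 17 adjusted over the list alone (mean -2.06, camera adjusted p = 4.46e-13, adjusted p = 0.21 with an estimated correlation), such as PLN (-5.51, SE 0.39) and PCP4 (-5.01, SE 0.47). All 18 luminal genes had negative changes and 4 were called, DPP4 (-4.59, SE 0.62), SPDEF (-1.84, SE 0.47), MSMB (-3.85, SE 1.09) and KRT18 (-1.02, SE 0.24). Adjusted over the list alone, 8 fell (mean -1.76, camera adjusted p = 3.88e-05, adjusted p = 0.21 with an estimated correlation). With the most variable feature per gene KRT18 turned to 0.39 (adjusted p = 0.643). Of 26 androgen receptor targets 5 fell, such as TRPM8, ABCC4 (-2.54, SE 0.62), TMPRSS2 (-3.61, SE 0.88) and C1orf116 (-2.07, SE 0.44), and 10 adjusted over the list alone (mean -1.17, camera adjusted p = 0.00568, adjusted p = 0.528 with an estimated correlation). The list mean for these targets was -2.27 on metastatic 2 and 0.24 on metastatic 4. Of the 35 genes reported higher in prostate cancer 10 fell, among them OR51E2, LUZP2 and ENTPD5 (-1.71, SE 0.31), and EZH2 rose. Adjusted over the list alone 15 fell and 1 rose (mean -1.62, camera adjusted p = 0.000109, adjusted p = 0.24 with an estimated correlation). In the promoter-hypermethylated list 7 genes fell, such as SFRP1 (-4.73, SE 0.41) and SLIT2 (-2.89, SE 0.41), and 8 adjusted over the list alone (mean -0.76, camera adjusted p = 0.00224, adjusted p = 0.523 with an estimated correlation). Of the WNT genes 4 fell, such as SFRP1 and SFRP4 (-4.69, SE 0.74), and 7 adjusted over the list alone (mean -0.94, camera adjusted p = 0.00617, adjusted p = 0.21 with an estimated correlation). Mast cell genes fell in 4 of 5, over all genes and adjusted over the list alone, with CPA3 at -4.30 (SE 0.47) and HDC at -4.68 (SE 0.61, list mean -2.62, camera adjusted p = 0.000229, adjusted p = 0.21 with an estimated correlation). T and NK cell genes fell in 6 of 13, with LCK at -2.66 (SE 0.49) and GZMK at -2.56 (SE 0.50), and 8 adjusted over the list alone (mean -1.52, camera adjusted p = 0.000125, adjusted p = 0.365 with an estimated correlation). B and plasma cell genes fell in 4 of 12, CD38 among them, with MZB1 at -1.87 (SE 0.36) and 5 adjusted over the list alone (mean -1.28, camera adjusted p = 0.0393, adjusted p = 0.528 with an estimated correlation). Fibroblast genes fell in 5 of 22 and rose in 1, with FMOD at -3.27 (SE 0.51) and MFAP4 at -2.62 (SE 0.43), and adjusted over the list alone, 8 fell and 1 rose (mean -0.95, camera adjusted p = 0.0047, adjusted p = 0.555 with an estimated correlation). Of 24 immediate early genes CCN2 (-4.57, SE 0.82) and EGR3 (-4.62, SE 0.98) fell, and adjusted over the list alone 10 fell and 1 rose (mean -1.33, camera adjusted p = 0.00594, adjusted p = 0.686 with an estimated correlation).

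Quantile normalization ended the calls of fibroblast (shift -0.42, adjusted p = 0.143), B cell (-0.55, 0.642), promoter-hypermethylated (-0.17, 0.324) and cancer-testis genes (0.39, 0.205). It left called but moved those of smooth muscle (-1.24), proliferation (0.84), T cell (-0.89) and WNT genes (-0.48). Leaving out metastatic 2 ended the call of androgen receptor targets (-0.76, 0.097), and metastatic 3 that of the promoter-hypermethylated list (-0.51, 0.1). Several single arrays did so for immediate early genes (metastatic 1 or 3, 0.0501 and 0.0953), lipid genes (localized 3 or 4 and metastatic 3 or 4, 0.0513 to 0.1), B cell genes (localized 3 and metastatic 1, 3 or 4, 0.0614 to 0.242) and cancer-testis genes (benign N1, localized 2 to 5 and metastatic 2 or 3, 0.0517 to 0.0953). Zeros as missing ended those of B cell (0.0551) and cancer-testis genes (0.562). By limma, 1309 genes changed, 409 (31.2%) higher and 900 lower. After quantile normalization 475 were called, 43.8% of them higher, and with the arrays centred on the median of their values other than 0 the share was 44.6% of 1127. The count was 841, 776, 840 and 675 without localized 1, 2, 4 and 5, 508 with array weights and 610 with only the arrays compared. Of the 64 named genes called here 48 kept their call in all 13 runs that left out 1 array and 38 under every other scaling. Among the genes given above, quantile normalization ended the calls of EZH2, DNMT3B, PRAME, MMP26, ALB, FABP1, EGR3, LCK, GZMK, MZB1, MFAP4 and FMOD. It also ended those of the luminal genes MSMB, SPDEF and KRT18 and of the androgen receptor targets TMPRSS2, ABCC4 and C1orf116. Centring on the median of values other than 0 ended those of MSMB and KRT18. Of the 13 runs MSMB lost its call in 10, SPDEF in 7, TMPRSS2 and HBB in 6, DNMT3B in 5, ABCC4 in 4, KRT18 in 3 and HP in 2.

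**Figure D3:**
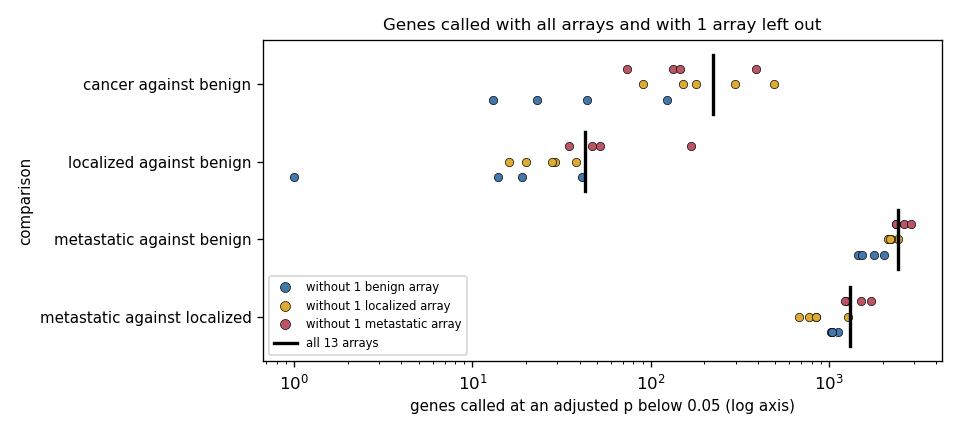
Number of genes called by limma at an adjusted p below 0.05 (horizontal log axis) in each comparison with all 13 arrays (vertical bars) and with 1 array left out (circles, coloured by the group of the array left out). The cancer against benign count ranged from 13 to 489, localized against benign from 1 to 169, metastatic against benign from 1463 to 2888 and metastatic against localized from 675 to 1718.

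The overlap of the cancer groups asked which genes changed in both localized and metastatic tissue against benign. DLX1, DLX2, HOXC6 and COL10A1 were among 5 genes higher in both, and CYP3A4, CYP3A7, CCK, KRT222, DPYS, EDN3 and MYLK among 34 genes lower in both. Both calls of HOXC6 rest on benign values that were all exact zeros. No gene was called in opposite directions. Lists drawn independently of each other would share 0.39 higher and 3.35 lower genes. Across genes, the log2 changes in both groups correlated at 0.56, against 0.53 in 100 simulations of unchanged groups that share the 4 benign arrays. Their covariance was 0.425 against 0.152. In these simulations at most 0 genes were called in both with the same direction, against the 39 observed. No simulated gene truly changed, so this 0 cannot tell how many changed genes would be shared. The simulations gave each gene 1 spread for all arrays, while ratios spread more widely on the metastatic arrays. With the benign arrays divided 2 and 2 between the comparisons, the correlation was 0.34 to 0.50 over 6 divisions and 0 to 11 genes were shared. The 39 shared genes became 1, 13 and 18 without benign N2, B1 and N1, 19, 24 and 13 without localized 2, 3 and 4, and 151 without metastatic 2. After quantile normalization 211 genes were shared.

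The last comparison set the 2 arrays titled normal against the 2 titled benign, which the series design pools. CCDC68 was the 1 gene called, listed at 0 on both benign-titled arrays and on all 9 cancer arrays, with a mean of 3.83 on the normal-titled arrays (adjusted p = 0.000102). Its call rests on values listed at 0. With zeros treated as missing it had too few values to be tested. Of the 15002 genes tested in that way 0 were called by limma and 608 had an unadjusted p below 0.05. With zeros as values, at an unadjusted p below 0.05 there were 864 genes where 846 are expected by chance. MYH11 had a change of 1.96 (SE 0.61, adjusted p = 0.674), DNMT3B of -1.87 (SE 0.59, adjusted p = 0.68) and GSTP1 of -0.76 (SE 1.27, adjusted p = 1). The count was 86 after quantile normalization, 186 with array weights, and 4, 3 and 2 without normal N1, normal N2 and benign B2. In the test on simulated data this comparison recovered 7% of the genes given a log2 change of 2.

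Of the 39 lists, 15 shifted in none of the 4 comparisons between disease groups, and their smallest camera adjusted p was 0.063 for ribosomal proteins, 0.0693 for club and hillock epithelium, 0.0853 for adrenal and kidney, 0.108 for HOX and developmental regulators and 0.115 for seminal vesicle. It was 0.164 for bone cells, 0.181 for myeloid cells, 0.253 for polycomb complex members and 0.347 for epithelial-mesenchymal transition. It was 0.425 for the DNA methylation machinery, 0.462 for lung, 0.495 for lymph node stroma, 0.498 for androgen synthesis and breakdown, 0.566 for tumor suppressors and oncogenes and 0.661 for adipocyte and skeletal muscle. In 23 of the 156 list tests, none of them called, the mean or the median had another sign than the test. Among the uncalled lists, metastatic 2 stood apart in ribosomal protein genes, with a mean of -1.25 against -0.16 to 0.01 on the other metastatic arrays.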

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

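The tests of wider ratios, of a benign sample under a metastatic title, of fewer detected features and of array scaling were chosen only after the results they measure were seen. Values were checked for arrays far from the rest of their group, for the genes chosen by the naming rule and the 39 list means. Of 648 groups 29 held such an array, and chance alone flags about 1 in 20, or 32.4. In benign tissue these were AURKA (0.29) and CDC20 (0.74) on N1, CNN1 (0.16), PLN (1.42) and PRAME (-0.14, with the other benign arrays listed at 0) on B2. On B1 they were KRT222 (2.20) and TNFRSF17 (2.53). In localized cancer they were the endothelium mean (-0.29), C1orf116 (-0.48), MMP26 (0.96) and SFRP4 (2.69) on localized 5, CAV1 (-2.90), CHGB (-4.08) and CPA3 (-1.74) on localized 3, IL11 (0.98) on localized 2, NCAM1 (-2.69) on localized 4 and NR4A1 (-0.94) on localized 1. In metastatic cancer they were the means of basal epithelium (1.55), lymph node stroma (0.015), ribosomal proteins (-1.25) and HOX and developmental regulators (-0.076) and the genes GSTP1 (0.64) and PMP2 (0.11) on metastatic 2, the genes CENPF (3.33), FAP (3.42), GZMA (-1.27), TKTL1 (0.078) and TNFRSF17 (-3.72) on metastatic 1, and RBPMS2 (-1.36) on metastatic 3.

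Among the named genes called in cancer against benign, the change against benign differed between metastatic and localized cancer by the test of the difference itself for MYLK (-3.43), CCDC178 (-2.65), RBFOX3 (-2.56), DLGAP5 (1.88) and DPT (-1.45). A signal also appeared in 9922 features without a gene name here, which the comparisons leave out: by limma 10 changed in cancer against benign, 11 in localized against benign, 1012 (459 higher) in metastatic against benign and 401 (143 higher) in metastatic against localized.

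Other divisions of the same arrays into groups of the same sizes tested whether chance can be excluded. It can for the number of genes in cancer against benign (1 of 100 divisions as large, the real 225, highest other 6), localized against benign (1 of 100, 43, highest other 1), metastatic against benign (1 of 35, 2441, highest other 3) and metastatic against localized (1 of 100, 1309, highest other 302). For the lists of metastatic against localized 1 of 100 divisions gave as many (the real 17, highest other 16). This passed the share set beforehand by a margin of 1 list. Not every division was drawn, and no other list count passed, so chance is not firmly excluded for these lists. The number of lists was 14 without localized 3 or without metastatic 3 and with zeros as missing, and 0 with an estimated correlation. Chance cannot be excluded for the number of lists in cancer against benign (32 of 100, 12, highest other 20), localized against benign (19 of 100, 13, highest other 19) and metastatic against benign (4 of 35, 15, highest other 21). The median number of lists called in the other divisions was 10, 9 and 9 in this order, and 10 for metastatic against localized. For the overlap 2 of 100 divisions gave as many genes (the real 39, highest other 790). These divisions mix all 3 groups and so remove both differences from benign tissue. They test whether the groups differ at all, and cannot tell whether more genes are shared than the shared benign arrays produce. With the benign arrays divided 2 and 2 between the comparisons, 0 to 11 genes were shared. What the divisions calling 790 and 302 genes have in common was not tested.

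Hepatocyte genes were higher on the metastatic arrays, with a list mean of 5.54 on metastatic 4. Wider ratios alone are argued against: after quantile normalization the shift against localized was 2.17 beside 2.62, and it stayed called by camera at the preset correlation. With an estimated correlation the list was not called (adjusted p = 0.365 with an estimated correlation on the deposited scale). Liver tissue in the sample may contribute, and the labels give no site: of a second list of 26 liver genes 57.7% had their highest value on metastatic 4 (exact 95% interval 36.9 to 76.6, chance 1 in 13 for arrays of equal spread), with a mean of 3.61 there and ALB at 9.54. The interval takes the genes as independent, which they are not, so it is too narrow. Ratios spread more widely on the metastatic arrays, so highest values fall there more often than 1 in 13. The lower bound did not pass the 50% set beforehand, and liver genes expressed by tumor cells, not tested separately, would raise this share as well, so both sources stay open.

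Metastatic 2 stood apart from the other metastatic arrays, with basal genes at 1.55, luminal genes at -3.18 and GSTP1 at 0.64. Further list means set metastatic 2 apart as well: bone cells (2.70), lymph node stroma (0.015), HOX and developmental regulators (-0.076) and ribosomal proteins (-1.25). Causes for these further lists were not tested. A benign sample under a metastatic title is argued against by its smooth muscle mean of -2.50, below all 4 benign arrays, and fewer detected features by its 16.5% of values listed at 0 against 19.5% on metastatic 3. Squamous epithelium or squamous differentiation of the tumor could be a source: of 19 squamous genes outside the basal list 73.7% had their highest value on metastatic 2 (exact 95% interval 48.8 to 90.9, mean 2.09), with SPRR2D at 6.29 and SPRR1A at 3.90. This interval also takes the genes as independent, and metastatic 2 is among the arrays with the wider ratios. The lower bound missed the 50% set beforehand, which keeps this open, and the test does not separate both forms.

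Genes reported as promoter-hypermethylated were lower in cancer than in benign tissue (mean -1.13, adjusted p = 0.344 with an estimated correlation, at which the call is lost). Array scaling as the whole cause of this difference is argued against: after quantile normalization the shift was -0.78 and stayed called, as it did in localized (-0.70) and metastatic tissue (-0.87) against benign. For the further difference of metastatic from localized cancer (-0.76) scaling stays open, since the shift was -0.17 after quantile normalization (adjusted p = 0.324). A smaller share of smooth muscle in the cancer samples may account for part of the lower values in cancer. This was tested on the 38 members that are in no other list. Within groups, arrays with lower smooth muscle genes had lower means of these 38 (r = 0.73 over 13 arrays, rho = 0.75, permutation p = 0.00418 adjusted over r and rho). Without the 2 arrays farthest in smooth muscle r was 0.74, while arrays far in the other list were kept. The correlation was computed only on the deposited scale, so it was not checked whether array scaling moves both lists together. The same 38 members had a mean of -1.01 in cancer against benign, and methylation, which was not measured, stays open as an untested explanation.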

How the results depend on the processing

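Treating exact zeros as missing and centring on the median of values other than 0 were chosen after the data were seen. Centring on the array median, features with a value on all arrays, no filter on missing values and a log2 change of at least 1 left every count of genes or lists within 1.5 times its value in each comparison they were run for. The first 3 of these hardly change the data, so their counts could not move far. The median over named features was -0.0056 on metastatic 4 and 0 elsewhere, and 37253 of 37260 features had a value on all arrays. Quantile normalization gave 638 genes for cancer against benign, 267 for localized against benign, 475 for metastatic against localized, 86 for normal against benign titles and 211 for the overlap, and zeros as missing gave 0 for normal against benign titles (limma), with CCDC68 not tested there. Variance with a trend and robust estimation gave 123 genes for cancer and 18 for localized against benign. Array weights gave 976 for cancer, 713 for localized, 508 for metastatic against localized and 186 for normal against benign titles. For cancer against benign the more variable 50% of the genes gave 355, and a 3-group fit 992 with cancer weighted by arrays and 1165 with equal weights, where the difference between the cancer groups no longer counts as spread. Only the arrays compared gave 231 genes for localized against benign, 1418 for metastatic against benign and 610 for metastatic against localized. With only the arrays titled benign as comparison 3 genes were called for cancer, 0 for localized and 759 for metastatic tissue, and with only those titled normal 49 for cancer and 1452 for metastatic tissue, from fewer arrays. A replicate block gave 487 genes for metastatic against localized. Arrays with the same number did not deviate together (r = -0.02, -0.19, -0.10 and -0.03). Those with different numbers had r from -0.10 to 0.12. Since other differences between the tissue pieces can hide a shared donor, this cannot settle whether the numbers pair samples. For the lists an estimated correlation gave 0 in all 4 comparisons. Directional fry gave 7 for cancer, 6 for localized, 17 for metastatic against benign and 9 for metastatic against localized. Mixed fry gave 22 for cancer, 12 for localized, 36 for metastatic against benign and 32 for metastatic against localized. Preranked enrichment, which like camera compares list members with other genes, gave 18, 14, 16 and 18 in the same order. Leaving out 1 array gave 13 (benign N2) to 489 (localized 5) genes for cancer against benign, 1 (benign N2) to 169 (metastatic 2) for localized against benign and 1463 (benign N1) to 2888 (metastatic 2) for metastatic against benign. It gave 675 (localized 5) to 1718 (metastatic 1) for metastatic against localized, 1 to 4 (normal N1) for normal against benign titles and 1 (benign N2) to 151 (metastatic 2) for the overlap. The lists ranged over 12 to 18, 11 to 15, 11 to 17 and 14 to 17 in the order of the report. The 1 reversed result was KRT18 in metastatic against localized (-1.02), at 0.39 with the most variable feature (adjusted p = 0.643) and -1.13 to -0.87 under its other alternatives (adjusted p = 0.0173 to 0.0737). Except where stated, the cause was not tested. Of the named genes, quantile normalization left 255 values on their side of the threshold, with 41 weaker and 29 stronger, and leaving out 1 array left 3754, with 403 weaker and 68 stronger. Of the list shifts 43 stayed called and 14 did not after quantile normalization, and 693 and 48 after leaving out 1 array. With the most variable feature 52 stayed and 5 did not, with zeros as missing 51 and 4, with only benign-titled arrays 36 and 4, with only normal-titled arrays 32 and 8, and with the block 15 and 2. Signal over background was not used here, so its limit on weak spots is known only through the values listed at 0.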

Other observations

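PRAME, an antigen of testis and many tumors, was listed at 0 on 3 of the 4 benign and 3 of the 5 localized arrays, at 0.88 and 0.85 on localized 2 and 5, and at 6.93, 3.86, 4.41 and 1.43 on metastatic 1 to 4. ERG stood at 3.29, 3.94 and 3.75 on localized 2, 4 and 5 and at 2.59 and 3.12 on metastatic 1 and 3, and at or below 0.21 on the other 8 arrays. ETV1 was 4.17 on localized 5 and at or below 1.65 elsewhere. These levels fall in some arrays of a group and not in others, which an average over the group hides.

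On metastatic 2 the bone cell list had a mean of 2.70 and the lung list of 1.08, while neither list shifted in any comparison. AKR1B10 was 7.63 on metastatic 2 and at or below 0.89 on every other array.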
